A study of Homo sapiens with 8 samples.

How the data were processed

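Total RNA from cultured human primary fibroblasts was profiled on 8 Affymetrix HG-U133 Plus 2.0 arrays, with 4 groups of 2 arrays. Per the labels, cells were transduced with a retrovirus expressing LacZ, a bacterial enzyme used as the control, or with retroviruses expressing the transcription factors p63 and KLF4. A pair of further groups received p63 and KLF4 and were labelled low calcium or high calcium, and the treatment protocol in the labels gives 1.2 mM calcium as the addition. The labels give DMEM with serum as the medium and a column kit for the RNA, and do not say what else differed between the p63+KLF4 group and its low calcium counterpart. No LacZ group with low or high calcium was analysed here. Nothing in the labels says that replicates came from separate cultures or donors, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

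The deposited values are linear probe set intensities, which the authors made with PLIER, per the submitters' processing notes. PLIER combines the probes of a probe set into 1 intensity. Its version, its settings and any scaling between arrays are not given in the sources used here. The median intensity over all probe sets was between 34.2 and 37.9 on the 8 arrays, and between 28.2% and 32.9% of the probe sets on an array read below 16. The ratio of the 3' to the 5' probe set of ACTB, a common measure of RNA integrity, was 1.34 and 1.49 in LacZ, 2.11 and 1.82 in p63+KLF4, 1.5 and 1.36 in low calcium, and 1.61 and 1.75 in high calcium. The same ratio of GAPDH lay between 0.928 and 1.07 on the 8 arrays. The hybridization control bioB, read from its 3' probe set, was 124 and 177 in LacZ, 206 and 209 in p63+KLF4, 132.5 and 127 in low calcium, and 123 and 109 in high calcium. Between replicates 0% of genes had exactly equal values, with no tolerance, and Pearson's r between replicates across genes was 0.988 in LacZ, 0.991 in p63+KLF4, 0.997 in low calcium and 0.997 in high calcium.

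Of the 54675 probe sets, 62 control probe sets were left out. The platform annotation used named 42898 probe sets, and 6 of these are among the 62 controls. Of the named probe sets 1801 carried several genes and were not used. A further 11721 had no gene in this annotation and were tested only for the closing section. Another 59 probe sets of XIST, TSIX and Y-linked genes were left out because they can reveal a donor's sex. The remaining 41032 probe sets with 1 gene represented 19740 genes, and each gene was read from its probe set with the highest mean log2 intensity over the 8 arrays. Gene symbols were matched to current ones through Entrez IDs for 41043 probe sets, and 0 symbols changed. The transcript of p63 was not analysed here because the annotation used pairs no probe set with it.

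Intensities were analysed as log2(intensity + 16), and every fold change below is on this scale, which understates the change of genes with low intensities. A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and with moderated variances that follow a trend with intensity. The p-values were adjusted with the Benjamini-Hochberg method over all genes within a comparison, and a gene with an adjusted p under 0.05 was called changed. The comparisons were p63+KLF4 versus LacZ and high calcium versus low calcium, then low calcium versus LacZ, high calcium versus LacZ and low calcium versus p63+KLF4. Values are given as mean intensity ± SD over 2 arrays, and log2 changes with the standard error of the fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

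A total of 24 gene lists were fixed before the data were examined, and some share members. They hold genes of basal keratinocytes, early keratinocyte differentiation, the cornified envelope and barrier, epithelial junctions and polarity, simple epithelium, fibroblast matrix, fibroblast identity and mesenchymal regulators, contractile and myofibroblast genes, cell cycle, p53 family targets, interferon response, inflammatory cytokines, immediate early and AP-1 genes, EGF receptor ligands and signalling, the Notch pathway, cholesterol and fatty acid synthesis, glycolysis and hypoxia, unfolded protein and amino acid stress, metallothioneins and calcium handling, and markers of melanocytes, endothelial cells, leukocytes and adipocytes. Each list was compared with all other genes with limma's camera and a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera was also run with a correlation estimated for each list (statmod 1.5.0), and fry was run to ask whether the genes of a list moved, on balance, in 1 direction. A further 6 lists were chosen after the data were seen, for complement, matrix metalloproteinases, antigen presentation, HOX genes, BMP-responsive genes that had been noticed and BMP-responsive genes not looked at before, and were adjusted over their own 30 tests. For every fixed list the number of members that rose and fell is also given adjusted over the list alone. Listed genes without a probe set used here were not measured, so coverage is incomplete. Of 28 basal keratinocyte genes listed 20 were measured, and of 39 HOX genes 28.

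The genes named were chosen by a rule fixed before the data were examined. It took every KLF4 probe set, the 8 largest rises and 8 largest falls of each of the first 2 comparisons and the 4 largest of each direction in the others. These had to pass the test with no overlap between the arrays of the groups compared, which 2 arrays against 2 reach often by chance. It also took up to 4 members of each list with the largest changes among those that passed, of which some that repeat a point are given only in the counts. Open reading frames, antisense and similar provisional names were skipped, and 1 result that the rule takes is not reported here.

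The alternatives chosen before the data were examined were quantile normalization, centring of each array on its median, a pseudocount of 1 or 64, leaving out dim genes, the mean of all probe sets of a gene, leaving out probe sets with the suffixes _x_at, _s_at or _a_at, fitting only the 4 arrays compared, variances without a trend, robust variances, the replicate number as a block, leaving out each array in turn, a change of at least 2-fold, and the estimated correlation for lists. These suffixes mark probes that may match more than 1 transcript, also of the same gene. A pair of alternatives was added after seeing the data, the block within the 4 arrays compared and array weights for each group.

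The procedure was tested on simulated data for 19740 genes, with the replicate spread of each group as measured, arrays drawn independently and 200 genes changed, 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold. For p63+KLF4 versus LacZ, 34.3% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold were called, and 40 of 19540 unchanged genes were called, which is 21.5% of the calls, a share that depends on the number of genes changed. For high calcium versus low calcium the shares were 13.4%, 85.1% and 100%, and 0 unchanged genes were called. In the measured data, deviations of same-numbered LacZ and p63+KLF4 arrays correlated at 0.66. The simulation leaves this out, so its shares for p63+KLF4 versus LacZ may not describe the measured arrays. The median replicate SD over the brighter 9870 genes was 0.145 in LacZ, 0.111 in p63+KLF4, 0.0509 in low calcium and 0.0492 in high calcium on the log2 scale, so the spread shared in the fit lies between that of the groups in the first comparison and that of the groups in the second. Fitted to the 4 arrays compared, the simulated calls were 1.49%, 26.9% and 95.5% with 1 unchanged gene for p63+KLF4 versus LacZ, and 71.6%, 100% and 100% with 18 unchanged genes for high calcium versus low calcium. In a simulation that shifted the cell cycle list in p63+KLF4 versus LacZ, camera called that list and 0 of the other 23. The noise of each gene was drawn separately, so the simulated genes were not correlated. In the measured data the estimated correlation reached 0.65, as for interferon response. The simulation therefore does not show how often the preset correlation calls a list of correlated genes without a change.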

Results

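Gene expression was measured in human primary fibroblasts, connective tissue cells, on 8 arrays. The groups were cells given LacZ, cells given p63 and KLF4, and cells given p63 and KLF4 under low or high calcium, with 2 arrays in each. Both introduced factors are known from keratinocytes, the main cells of the epidermis, where p63 maintains basal cells and KLF4 acts late in the formation of the barrier. Raised calcium is the usual trigger of differentiation in cultured keratinocytes. The design therefore asks which genes the introduced factors change in fibroblasts, and which genes respond to calcium in cells that carry them.

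KLF4, 1 of the introduced genes, was read by 2 probe sets that moved in opposite directions. The first read 52.8 ± 1.56 (SD, n = 2) in LacZ, 807 ± 284 in p63+KLF4, 856 ± 70.2 in low calcium and 1140 ± 131 in high calcium. It was 11.6-fold higher in p63+KLF4 than in LacZ (log2 change 3.54 ± 0.21 SE; limma adjusted p = 3.79e-06). The second read 867 ± 38.5 in LacZ, 311 ± 97.3 in p63+KLF4, 595 ± 46.5 in low calcium and 830 ± 39.5 in high calcium. It was 2.76-fold lower in p63+KLF4 than in LacZ (log2 change -1.46 ± 0.18 SE; adjusted p = 0.000447). Between high and low calcium the changes of 0.40 ± 0.21 and 0.47 ± 0.18 did not pass (adjusted p = 0.239 and 0.112). Fitted to only the 4 arrays compared, both passed (adjusted p = 0.00543 and 0.000829), and the second also passed after quantile normalization (0.04) and without p63+KLF4 replicate 1 (0.0185) or 2 (0.0178). Against LacZ, the first probe set was 12.7-fold higher in low calcium and 16.7-fold higher in high calcium. The second changed by -0.53 in low calcium (adjusted p = 0.0561, or 0.00747 and 0.00716 without p63+KLF4 replicate 1 or 2) and by -0.06 in high calcium (0.829).

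**Figure D1:**
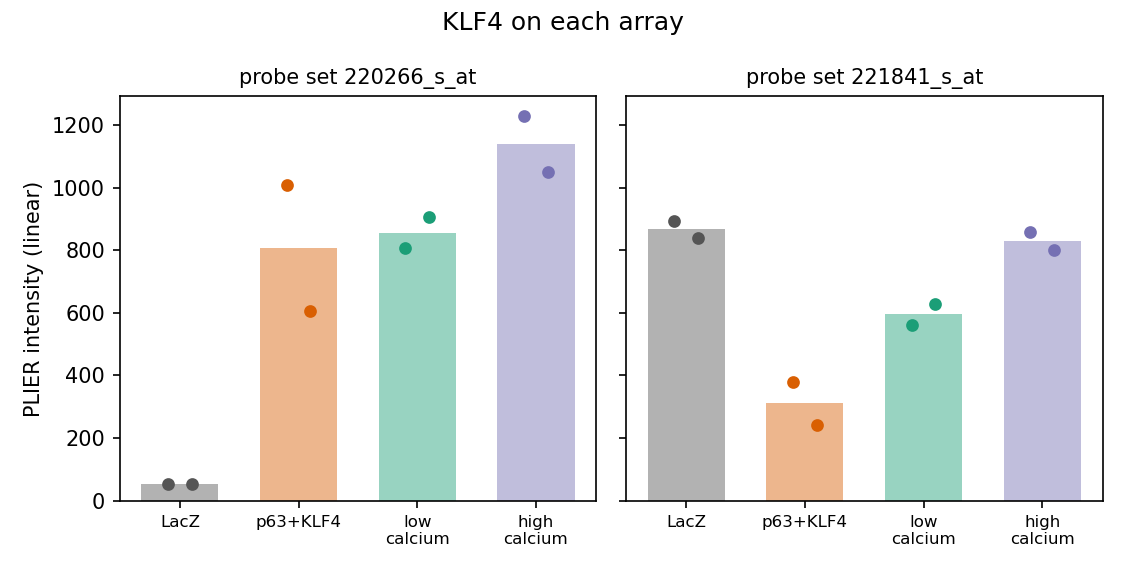
Linear PLIER intensity of both KLF4 probe sets on each of the 8 arrays, with points for arrays and bars for the mean of 2 arrays. The mean of the first probe set, on the left, is 52.8 in LacZ and 807 in p63+KLF4, and that of the second, on the right, is 867 in LacZ and 311 in p63+KLF4.

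In p63+KLF4 versus LacZ, 14 of 20 genes of basal keratinocytes rose and 11 of 15 contractile genes fell (adjusted p = 0.077 and adjusted p = 0.27 with an estimated correlation). KRT14, a keratin filament protein of basal keratinocytes, rose 496-fold, from 1.32 ± 1.83 (SD, n = 2) to 8560 ± 150 (log2 change 8.96 ± 0.09 SE; limma adjusted p = 5.07e-10). GJB2, a gap junction protein, rose 145-fold to 2500 ± 285, and AQP3, a water and glycerol channel of the epidermis, rose 75.4-fold to 3180 ± 186. The largest falls were in CEMIP, which takes part in hyaluronan breakdown (17.1-fold lower), and in SLC38A11, a putative amino acid transporter (12.2-fold lower). CEMIP has 2 probe sets, of which 1 passed and the other changed by 0.21 on the log2 scale. CNN1, a calponin of contractile cells, was 6.94-fold lower (log2 change -2.80 ± 0.17 SE; adjusted p = 1.18e-05), and THY1, a surface protein of fibroblasts, was 6.37-fold lower.

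Among the other largest rises were CD24, a surface glycoprotein (120-fold), ACKR3, a chemokine receptor (119-fold), EPPK1, a cytolinker of epithelia (53.3-fold), and MGP, an inhibitor of calcification (51.7-fold). The log2 change of EPPK1, 5.74, was 5.05 without p63+KLF4 replicate 1 and 6.42 without replicate 2. The adjusted p of these 4 genes lay between 1.06e-09 for ACKR3 and 1.23e-05 for EPPK1. The MGP call ended when probe sets with the suffixes _x_at, _s_at or _a_at were left out. Its other probe set, which then stands for the gene, had a log2 change of 0.21 (limma adjusted p = 0.523). The other largest falls were KRTAP1-5, a hair keratin associated protein (10.7-fold lower), APCDD1, an inhibitor of Wnt signalling (10.5-fold), TRPV2, a cation channel (9.92-fold), ANGPT1, a ligand of the receptor TEK (8.49-fold), SH3GL2, an endophilin (7.55-fold), and SYNPO2, an actin-binding protein (7.51-fold). The log2 change of APCDD1, -3.39, was -3.98 without LacZ replicate 1 and -2.80 without replicate 2. APCDD1 and TRPV2 have 2 probe sets each, of which 1 passed, and the others changed by -0.41 and -0.43.

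Of 20 measured basal keratinocyte genes, 14 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.53e-10, or adjusted p = 0.077 with an estimated correlation). Besides KRT14, the members with the largest rises were KRT16, a keratin of activated keratinocytes (33.0-fold), S100A2, a calcium-binding protein of basal cells (28.8-fold), and SERPINB5, a serpin (23.1-fold). The other of the 2 SERPINB5 probe sets did not pass (log2 change -0.25). Among 23 genes of early differentiation, 10 rose and 1 fell on both adjustments (camera adjusted p = 0.00117; adjusted p = 0.077 with an estimated correlation). TGM1, the transglutaminase that cross-links the cornified envelope, rose 13.8-fold, and LYPD3 rose 4.08-fold. Of 36 genes of the cornified envelope and barrier, 16 rose and 3 fell, and 16 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.077 with an estimated correlation). The envelope precursors SPRR1A and SPRR3 rose 44.2-fold and 36.8-fold, and FLG, which encodes the filament-aggregating protein filaggrin, rose 14.1-fold. The log2 change of FLG, 3.82, was 2.70 without p63+KLF4 replicate 1 and 4.94 without replicate 2. Of 33 genes of epithelial junctions and polarity, 15 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.14e-05; adjusted p = 0.077 with an estimated correlation). Its largest rises were the desmosomal genes PKP1 (28.1-fold) and DSG2 (12.6-fold) and MAL2, a protein of apical transport (14.3-fold). Without p63+KLF4 replicate 1 or 2 the log2 change of PKP1, 4.81, was 4.18 and 5.45.

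Genes of fibroblasts fell in part. Of 15 contractile and myofibroblast genes, 0 rose and 11 fell, and 13 fell adjusted over the list alone (camera adjusted p = 2.06e-07; adjusted p = 0.27 with an estimated correlation). After CNN1 the largest falls were MYL9, a myosin light chain (5.13-fold lower), ACTG2, a smooth muscle actin (4.68-fold), and TAGLN, an actin cross-linker (4.26-fold). Of 28 genes of fibroblast identity and mesenchymal regulation, 4 rose and 14 fell on both adjustments (camera adjusted p = 0.00137; adjusted p = 0.29 with an estimated correlation), with MME, a surface peptidase, 5.96-fold lower and PDGFRA, a growth factor receptor, 2.71-fold lower. The 34 fibroblast matrix genes moved both ways, with 7 that rose and 10 that fell, or 8 and 11 adjusted over the list alone (camera adjusted p = 0.433). VCAN, a matrix proteoglycan, rose 4.53-fold and EFEMP1 rose 2.83-fold, while FBLN5, an elastic fibre protein, was 6.84-fold lower. Of 12 genes of EGF receptor signalling, 1 rose and 9 fell on both adjustments (camera adjusted p = 4.15e-05; adjusted p = 0.077 with an estimated correlation), among them the feedback inhibitors DUSP4 (5.21-fold lower) and SPRY4 (2.62-fold lower). Without LacZ replicate 1 or 2 the log2 change of DUSP4, -2.38, was -3.02 and -1.75. Of 7 metallothioneins, which bind zinc and copper, 0 rose and 5 fell, and 7 fell adjusted over the list alone (camera adjusted p = 0.00946; adjusted p = 0.56 with an estimated correlation). Their falls were small, with MT1M 1.91-fold lower, and without p63+KLF4 replicate 1 the adjusted p of MT1M was 0.0569, as it was 0.0725 when only the 4 arrays compared were fitted.

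The other lists were not called in p63+KLF4 versus LacZ. In the Notch pathway 8 of 16 genes rose and 2 fell on both adjustments (camera adjusted p = 0.0775), and the ligands JAG2 and JAG1 rose 16.2-fold and 7.96-fold. After each array was centred on its median, 5 rose and 3 fell and the list was called (0.0206). As deposited, the Notch list had a camera adjusted p of 0.27 with an estimated correlation. In the cell cycle list 9 of 31 genes rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.116), and 3 rose and 2 fell after centring. Of 10 simple epithelium genes 2 rose and 3 fell on both adjustments (camera adjusted p = 0.53), and KRT19, a keratin of simple epithelia, was 7.07-fold lower. Of 17 p53 family targets 6 rose and 4 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.56), with TP53INP1 2.46-fold higher and the cell cycle inhibitor CDKN1A 2.08-fold lower. Of 18 immediate early and AP-1 genes 2 rose and 5 fell on both adjustments (camera adjusted p = 0.104), with JUNB 3.6-fold higher and KLF2 7.06-fold lower. Of 21 cytokine genes 5 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.936), and IL1A rose 3.32-fold; after centring 4 rose and 4 fell. Of 21 interferon response genes 0 rose and 1 fell, and none passed adjusted over the list alone (camera adjusted p = 0.82). Cholesterol and fatty acid synthesis had 1 rise and 2 falls among 17 genes, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.865). Glycolysis and hypoxia had 3 rises and 4 falls among 18, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.664), with the vasodilator peptide ADM 3.56-fold lower. Unfolded protein and amino acid stress had 5 rises and 2 falls among 17, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.596), with PSAT1, an enzyme of serine synthesis, 1.93-fold higher; after centring 4 rose and 4 fell. Calcium handling had 3 rises and 4 falls among 19, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.49), with the plasma membrane calcium pump ATP2B1 2.09-fold lower. The median and mean log2 change had opposite signs for matrix genes (0.01 and -0.11), interferon response (0.11 and -0.01), cytokines (-0.01 and 0.12) and glycolysis (0.03 and -0.07).

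The lists of markers of other cell types were not called. Of 10 endothelial markers 2 rose and 0 fell on both adjustments (camera adjusted p = 0.856): TEK, the receptor of angiopoietins, rose 16.3-fold to 1480 ± 62.6 and the junction protein CLDN5 rose 3.89-fold. The median of that list was -0.09 on the log2 scale and its mean 0.51, and for leukocyte markers they were -0.04 and 0.11, with a test direction of lower. The other of the 2 TEK probe sets did not pass (log2 change -0.18). Of 8 melanocyte markers 1 rose and 2 fell (camera adjusted p = 0.399), of 10 leukocyte markers 1 rose and 0 fell (0.865), and of 9 adipocyte markers 1 rose and 3 fell (0.49), each with the same counts adjusted over the list alone. Among these, KIT was 2.81-fold lower, CD14 3.32-fold higher, and PPARG, a regulator of fat cells, 3.15-fold lower. The ACTB 3' to 5' ratio was 2.11 and 1.82 in p63+KLF4 against 1.34 and 1.49 in LacZ, and the hybridization control bioB read 206 and 209 against 124 and 177.

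**Figure D2:**
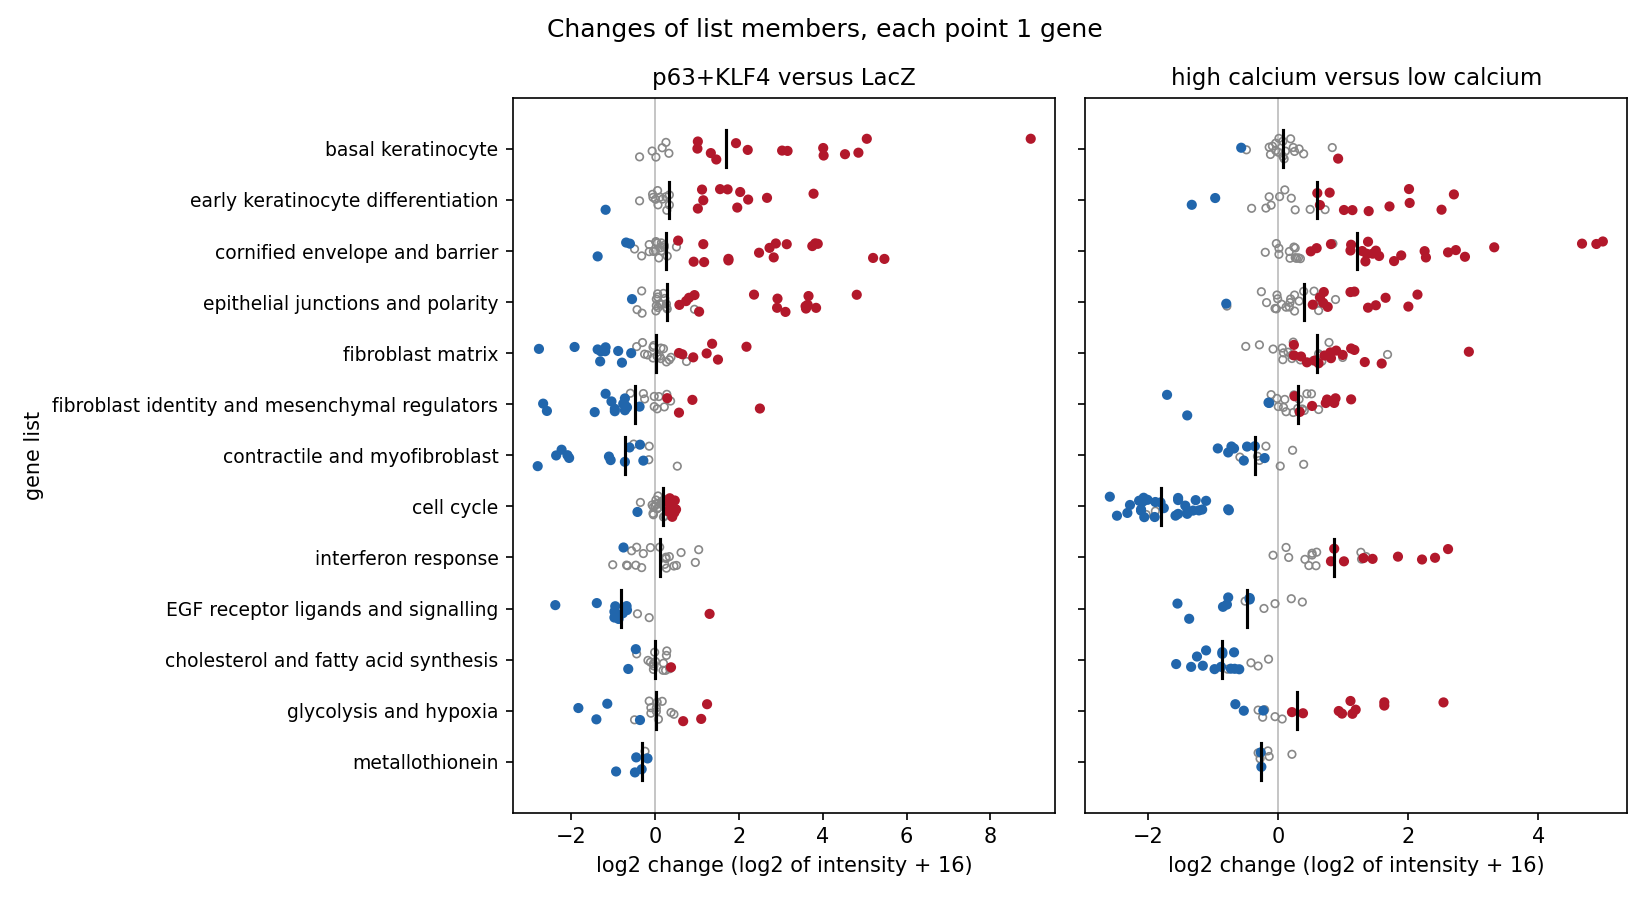
Log2 change of each measured gene of 13 lists in p63+KLF4 versus LacZ and in high calcium versus low calcium, with filled red points for genes that rose, filled blue points for genes that fell, open points for genes that did not pass and a black line at the median. The basal keratinocyte list has its median at 1.70 in the first comparison and at 0.07 in the second, and the cell cycle list at 0.19 and -1.81.

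Over all 19740 genes, 5191 changed in p63+KLF4 versus LacZ, 3212 higher and 1979 lower, and 1338 of them by at least 2-fold. The median change of all genes was 0.02 as deposited and -0.13 after each array was centred on its median, so small changes are relative to the scaling: the split was 2502 higher and 2509 lower after quantile normalization and 2069 higher and 3806 lower after centring. Of the 24 lists 8 were called, 0 with an estimated correlation, and fry called 15. Fitted to only the 4 arrays compared, 2174 genes passed, of which 2170 were among the 5191, and both fits treat the arrays as independent. Leaving out dim genes ended the call on early differentiation (adjusted p = 0.0811).

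In high calcium versus low calcium, 23 of 36 genes of the cornified envelope and barrier rose and 29 of 31 cell cycle genes fell (adjusted p = 0.015 and adjusted p = 0.053 with an estimated correlation). The calcium-binding proteins S100A9, S100A8 and S100A7, which keratinocytes make during inflammation and wound repair, rose 31.8-fold, 29.6-fold and 25.4-fold. S100A9 reached 494 ± 46.1 (SD, n = 2) from a low calcium level at the bottom of the scale (log2 change 4.99 ± 0.13 SE, limma adjusted p = 2.01e-06). When probe sets with the suffixes _x_at, _s_at or _a_at were left out, the other S100A8 probe set stood for that gene. It changed by 0.09 on the log2 scale (limma adjusted p = 0.765). PI3, the protease inhibitor elafin, rose 9.96-fold to 635 ± 37.0. CDC20, an activator of mitotic exit, was 6.02-fold lower at 335 ± 11.5 against 2100 ± 135 (log2 change -2.59 ± 0.09 SE; adjusted p = 4.70e-06), and RRM2, a subunit of the enzyme that makes deoxynucleotides, was 5.59-fold lower.

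The other largest rises were SERPING1, the inhibitor of complement C1 (12.5-fold), TMEM100, a membrane protein (10.3-fold), C3, the central complement component (9.54-fold), and MMP9, a gelatinase (9.43-fold). The other largest falls were TLL2, a metalloprotease (6.76-fold lower), the mitotic kinesins KIF23 (5.52-fold) and KIF18B (5.18-fold), LIPG, a lipase (5.08-fold), OXTR, the oxytocin receptor (5.03-fold), and AURKA, a mitotic kinase (4.98-fold).

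Of 31 measured cell cycle genes 0 rose and 29 fell, and 30 fell adjusted over the list alone (camera adjusted p = 9.57e-29; adjusted p = 0.053 with an estimated correlation). AURKB, another mitotic kinase, was 4.85-fold lower. In low calcium 4 genes of this list were higher and 10 lower than in LacZ (camera adjusted p = 0.613), and 1 was higher and 12 were lower than in p63+KLF4 (0.0639, or 0.0455 after centring with adjusted p = 0.62 with an estimated correlation). Of 36 genes of the cornified envelope and barrier 23 rose and 0 fell, and 24 rose adjusted over the list alone (camera adjusted p = 8.12e-16). This was the only call of the 11 in this comparison that held with an estimated correlation (adjusted p = 0.015 with an estimated correlation). Among 23 early differentiation genes 11 rose and 2 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.000158; adjusted p = 0.087 with an estimated correlation). LYPD3 rose 6.49-fold, KRT13, a keratin of mucosal epithelia, 5.70-fold, GRHL3, a transcription factor of the barrier, 4.04-fold, and KRTDAP 4.02-fold. Of 33 junction and polarity genes 12 rose and 1 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 7.89e-05; adjusted p = 0.094 with an estimated correlation), with the desmosomal cadherins DSC2, DSG3 and DSC3 rising 4.41-fold, 3.15-fold and 2.83-fold.

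Fibroblast matrix genes rose as well. Of 34 members 16 rose and 0 fell, and 23 rose adjusted over the list alone (camera adjusted p = 5.3e-07; adjusted p = 0.47 with an estimated correlation). MFAP4, a microfibril protein, rose 7.65-fold to 826 ± 99.7, and EFEMP2 and MFAP2, of elastic fibres and microfibrils, rose 2.51-fold and 2.25-fold. Of 28 genes of fibroblast identity 8 rose and 4 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0114; adjusted p = 0.48 with an estimated correlation), and CDH2, the cadherin of mesenchymal cells, was 3.28-fold lower. This call ended with the mean of all probe sets of a gene (adjusted p = 0.114). Of 15 contractile genes 0 rose and 8 fell, and 9 fell adjusted over the list alone (camera adjusted p = 0.0047; adjusted p = 0.56 with an estimated correlation), with CCN2, a matricellular protein induced by TGF-beta, 1.65-fold lower.

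Of 21 interferon response genes 9 rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 3.16e-06; adjusted p = 0.56 with an estimated correlation), with IFI44L and IFI27 rising 6.12-fold and 5.32-fold. Of 17 genes of cholesterol and fatty acid synthesis 0 rose and 13 fell, and 14 fell adjusted over the list alone (camera adjusted p = 5.87e-08; adjusted p = 0.47 with an estimated correlation), with DHCR7, the last enzyme of cholesterol synthesis, 2.97-fold lower. Of 12 genes of EGF receptor signalling 0 rose and 7 fell, or 1 and 7 adjusted over the list alone (camera adjusted p = 0.00771; adjusted p = 0.17 with an estimated correlation), with the ligand HBEGF 2.58-fold lower. Of 18 genes of glycolysis and hypoxia 10 rose and 3 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0336; adjusted p = 0.59 with an estimated correlation), with EGLN3, an oxygen sensor, rising 5.82-fold and PDK1, which restrains pyruvate oxidation, 3.10-fold. The glycolysis call ended without p63+KLF4 replicate 1 or 2 (adjusted p = 0.0593 in both), low calcium replicate 1 (0.0525) or high calcium replicate 1 (0.0563), with a pseudocount of 1 (0.0543) or 64 (0.0566), and when only the 4 arrays compared were fitted (0.0682).

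The remaining lists were not called in high calcium versus low calcium. Of 20 basal keratinocyte genes 1 rose and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.609), and KRT14 read 7420 ± 163 in high and 7430 ± 291 in low calcium. Of 10 simple epithelium genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.956), with MUC1, a surface mucin, 2.08-fold higher and KRT18 1.68-fold lower. Of 17 p53 family targets 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.797), with SESN2 1.64-fold higher; after quantile normalization 4 rose and 1 fell. Of 21 cytokine genes 2 rose and 3 fell on both adjustments (camera adjusted p = 0.581), with the chemokine CXCL6 2.52-fold higher and PTGS2, the inducible cyclooxygenase, 3.26-fold lower. Of 18 immediate early and AP-1 genes 3 rose and 6 fell on both adjustments (camera adjusted p = 0.377), with EGR3 2.13-fold higher and FOSL1 2.88-fold lower. In the Notch pathway 3 of 16 genes rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.581). Of 17 genes of unfolded protein and amino acid stress 4 rose and 4 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.752), with VLDLR, a lipoprotein receptor, 2.03-fold higher and SDF2L1 1.78-fold lower. Of 7 metallothioneins 0 rose and 2 fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.173). Calcium handling had 4 rises and 3 falls among 19 genes on both adjustments (camera adjusted p = 0.581), with S100P, another calcium-binding S100 protein, 3.16-fold higher. The median and mean log2 change were -0.09 and 0.03 for p53 family targets, and -0.10 and -0.05 for simple epithelium, where the test direction was higher.

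Among markers of other cell types, 2 of 10 endothelial markers rose and 0 fell (camera adjusted p = 0.305), 1 of 8 melanocyte markers rose and 0 fell (0.797), 0 of 10 leukocyte markers rose and 1 fell (0.567), and 1 of 9 adipocyte markers rose and 1 fell (0.956). The counts were the same adjusted over the list alone, and the median and mean of the adipocyte list were -0.06 and 0.01. CLDN5 rose 2.97-fold, PMEL, a melanosome protein, 2.00-fold and CFD, complement factor D, 2.76-fold, while LAPTM5 was 2.42-fold lower. The ACTB 3' to 5' ratio was 1.61 and 1.75 in high calcium against 1.5 and 1.36 in low calcium.

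**Figure D3:**
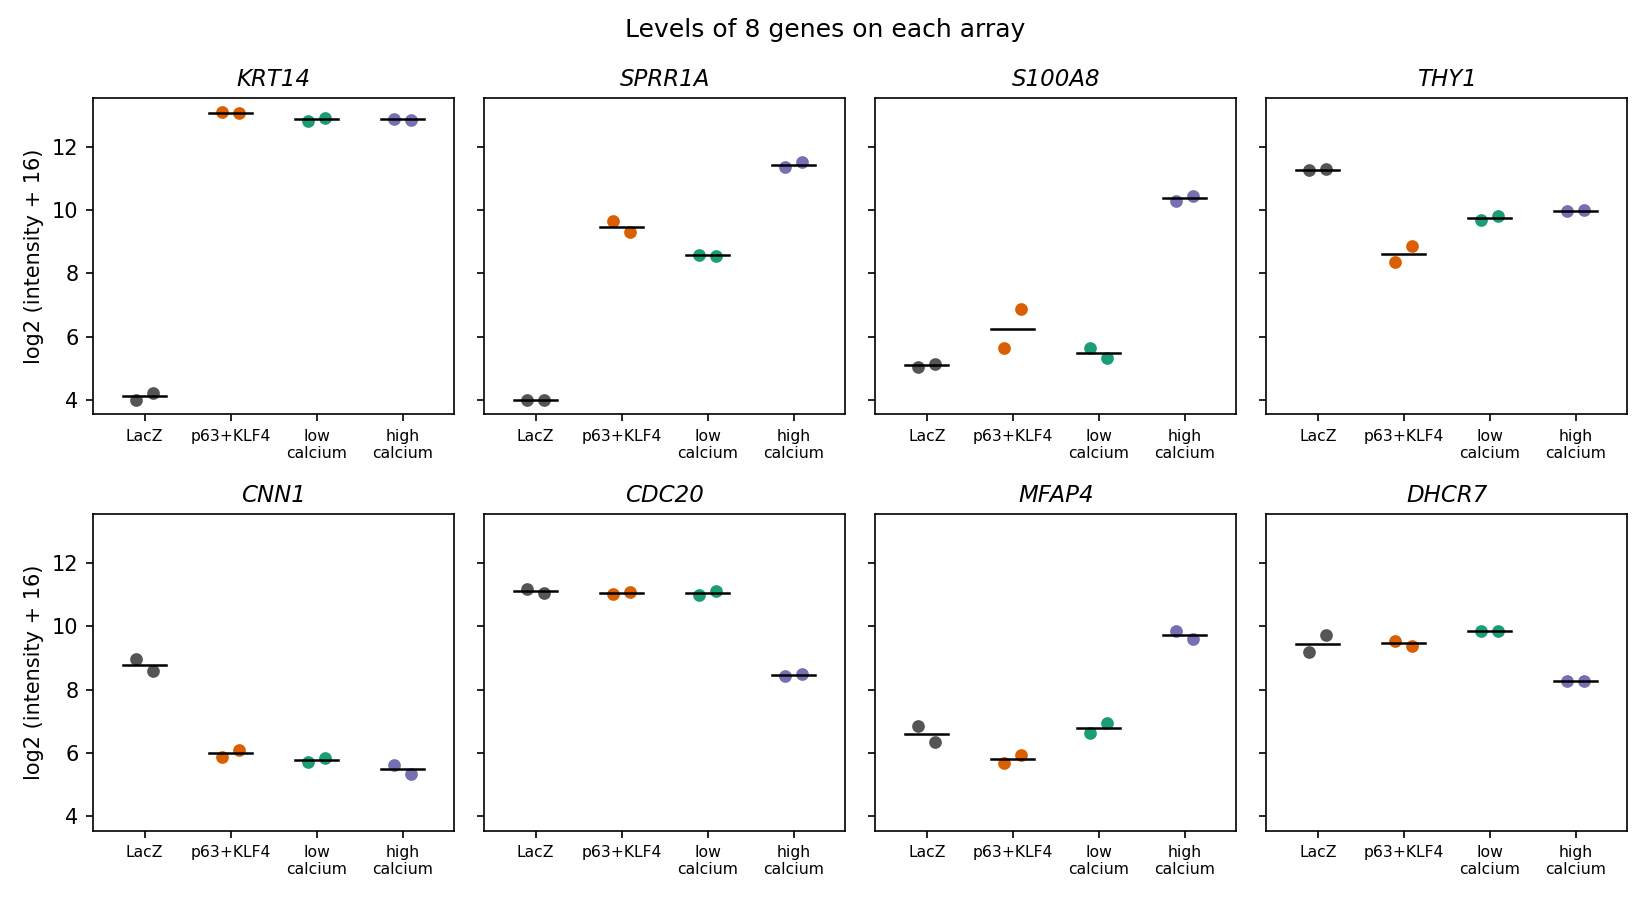
Level of 8 genes as log2(intensity + 16) on each of the 8 arrays, with a line at the mean of the 2 arrays of a group. KRT14 is lowest in LacZ, where its mean intensity is 1.32, and CDC20 is lowest in high calcium, where its mean intensity is 335.

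Over all 19740 genes, 4523 changed in high calcium versus low calcium, 2033 higher and 2490 lower, and 954 of them by at least 2-fold. The split was 2656 higher and 2173 lower after quantile normalization and 1563 higher and 3503 lower after each array was centred on its median. Of the 24 lists 11 were called, 1 with an estimated correlation, and fry called 11. Fitted to only the 4 arrays compared, 8690 genes passed, all 4523 among them, while 2301 and 1919 passed without low calcium replicate 1 or 2 and 2120 and 2118 without high calcium replicate 1 or 2. Leaving out dim genes ended the calls on early differentiation (adjusted p = 0.252), contractile genes (0.0801), EGF receptor signalling (0.09) and glycolysis (0.105).

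The 2 comparisons share no array and were set against each other across genes, which are not independent replicates. Their log2 changes had a Pearson's r of 0.08 and a Spearman's rank correlation of -0.04 over 19740 genes. Of the genes higher in p63+KLF4 than in LacZ, 603 were also higher in high than in low calcium, where independent lists would share 330.8, and 635 were lower, against 405.2. Of the genes lower in p63+KLF4, 313 were higher in high calcium, against 203.8, and 331 were lower, against 249.6. Both comparisons use the same variance of each gene, from the fit to all arrays, so the counts for independent lists are not those that unrelated changes would give.

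Low calcium versus LacZ had the same 4 largest rises as p63+KLF4 versus LacZ. KRT14 rose 431-fold, to 7430 ± 291 (log2 change 8.75 ± 0.09 SE; limma adjusted p = 6.16e-10), and GJB2, CD24 and ACKR3 rose 94.6-fold, 86.4-fold and 80.7-fold. The largest falls were STMN2, a tubulin-binding protein (27.0-fold lower), MMP3, the protease stromelysin (15.2-fold), SLC38A11 (13.4-fold) and KRTAP1-5 (12.9-fold). Of the 24 lists 9 were called and 0 with an estimated correlation. Those called as higher were basal keratinocyte genes, where 15 of 20 rose and 1 fell (camera adjusted p = 1.99e-11; adjusted p = 0.17 with an estimated correlation), junctions and polarity, where 14 of 33 rose and 3 fell (7.64e-05; adjusted p = 0.17 with an estimated correlation), the cornified envelope, where 12 of 36 rose and 5 fell (0.0076; adjusted p = 0.18 with an estimated correlation), the Notch pathway, where 7 of 16 rose and 3 fell (0.0133; adjusted p = 0.19 with an estimated correlation) and cholesterol synthesis, where 6 of 17 rose and 0 fell (0.0103; adjusted p = 0.74 with an estimated correlation). Those called as lower were contractile genes, where 13 of 15 fell (5.51e-06; adjusted p = 0.3 with an estimated correlation), fibroblast identity (0.00331; adjusted p = 0.31 with an estimated correlation), EGF receptor signalling (0.0076; adjusted p = 0.19 with an estimated correlation) and metallothioneins (0.0076; adjusted p = 0.52 with an estimated correlation). The cholesterol call ended without LacZ replicate 1 (adjusted p = 0.191), without dim genes (0.16) and without suffixed probe sets (0.146), and the Notch call without suffixed probe sets (0.083). In all, 6678 genes changed, 2961 higher and 3717 lower, and 3784 and 3530 passed without low calcium replicate 1 or 2.

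In high calcium versus LacZ, KRT14 rose 431-fold to 7420 ± 163 (log2 change 8.75 ± 0.09 SE; limma adjusted p = 6.18e-10), GJB2 rose 256-fold, and the envelope precursors SPRR1A and SPRR3 rose 173-fold and 137-fold. MMP3 was 41.2-fold lower, KRTAP1-5 34.9-fold, OXTR 29.8-fold and SSTR1, a somatostatin receptor, 27.5-fold. Of the 24 lists 11 were called, and the cornified envelope, where 23 of 36 genes rose and 0 fell, was the 1 call kept with an estimated correlation (camera adjusted p = 1.03e-10; adjusted p = 0.033 with an estimated correlation). In the cell cycle list 0 of 31 genes rose and 28 fell (camera adjusted p = 1.12e-15; adjusted p = 0.066 with an estimated correlation), and of 15 contractile genes 14 fell (5.9e-07; adjusted p = 0.24 with an estimated correlation). Of 34 matrix genes 16 rose and 5 fell (camera adjusted p = 0.00612; adjusted p = 0.68 with an estimated correlation), a call that ended without LacZ replicate 2 (adjusted p = 0.0613). Of 23 early differentiation genes 15 rose and 1 fell (camera adjusted p = 8.62e-06; adjusted p = 0.051 with an estimated correlation), of 16 Notch pathway genes 8 rose and 1 fell (0.00873; adjusted p = 0.12 with an estimated correlation), and of 17 stress genes 9 rose and 3 fell (0.0391; adjusted p = 0.3 with an estimated correlation). Leaving out dim genes ended the calls on early differentiation (0.0546) and stress (0.0894), and leaving out suffixed probe sets ended those on the Notch pathway (0.179) and stress (0.707). In all, 8369 genes changed, 3537 higher and 4832 lower, against 2740 higher and 7259 lower after each array was centred on its median, which moved the median change of all genes from -0.08 to -0.24. The ACTB 3' to 5' ratio was 1.61 and 1.75 in high calcium against 1.34 and 1.49 in LacZ.

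In low calcium versus p63+KLF4 few genes moved far. CTSG, the protease cathepsin G, was 4.42-fold higher in low calcium, at 126 ± 2.97 (SD, n = 2; log2 change 2.14 ± 0.12 SE; limma adjusted p = 0.000934). The chemokine CXCL6 was 3.93-fold higher, the scavenger receptor COLEC12 3.75-fold and the basal keratin KRT15 3.22-fold. SPP1, the matrix protein osteopontin, was 4.65-fold lower, STMN2 4.49-fold, TNFSF10, the death ligand TRAIL, 5.29-fold, and DLX2, a homeobox factor, 6.12-fold. Without low calcium replicate 1 or 2 the adjusted p was 0.0752 and 0.0589 for CXCL6 and 0.12 and 0.107 for COLEC12, and without replicate 1 it was 0.0579 for KRT15 and 0.0513 for TNFSF10. The DLX2 call (adjusted p = 0.0469) ended under quantile normalization (0.0761), under centring (0.0686) and without p63+KLF4 replicate 1 (0.159) or 2 (0.0679), low calcium replicate 1 (0.271) or 2 (0.19) or high calcium replicate 1 (0.0915) or 2 (0.0917), and also with either other pseudocount, without a variance trend and with robust variances. The second KLF4 probe set was 1.91-fold higher in low calcium (adjusted p = 0.0225), and did not pass without p63+KLF4 replicate 2 (0.0537), low calcium replicate 1 (0.185) or 2 (0.196) or high calcium replicate 1 (0.063) or 2 (0.0632).

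Genes of cholesterol and fatty acid synthesis were higher as a list in low calcium than in p63+KLF4, with 2 of 17 members that rose and 0 that fell, and 4 that rose adjusted over the list alone (camera adjusted p = 6.05e-06; adjusted p = 0.6 with an estimated correlation). The cytokine list, with 1 rise and 2 falls among 21 genes, and the stress list, with 3 rises and 2 falls among 17, were called at an adjusted p of 0.0493 each (adjusted p = 0.61 and 0.45 with an estimated correlation). Both calls ended with a pseudocount of 1 (0.0774) or 64 (0.062). The cytokine call ended under quantile normalization (0.0939), centring (0.09) and without p63+KLF4 replicate 1 (0.477), the stress call ended without p63+KLF4 replicate 2 (0.0801) or low calcium replicate 2 (0.0807), and both ended without high calcium replicate 1 or 2 (0.0504). The ACTB 3' to 5' ratio was 1.5 and 1.36 in low calcium against 2.11 and 1.82 in p63+KLF4, and the hybridization control bioB read 132.5 and 127 against 206 and 209. In all, 1933 genes changed, 315 higher and 1618 lower, against 569 higher and 781 lower after quantile normalization and 497 and 843 after centring. The number that passed was 3604 and 3595 without LacZ replicate 1 or 2, 1067 and 960 without p63+KLF4 replicate 1 or 2, 23 and 64 without low calcium replicate 1 or 2, and 766 and 764 without high calcium replicate 1 or 2.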

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

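The test of probe sets without a gene name was chosen after the data were seen. The 11721 probe sets with no gene in the annotation used enter no comparison of the report. A smaller share of them differed than of the 19740 genes, but these shares are not like for like. Each gene was read from its probe set with the highest mean log2 intensity, while the 11721 probe sets were not selected by level. No conclusion about transcripts without a gene name is drawn from the difference. Of the 19740 genes 5191 changed in p63+KLF4 versus LacZ and 4523 in high calcium versus low calcium. Of the 11721 probe sets, 544 were higher in p63+KLF4 than in LacZ and 592 were lower, and 33 of the former rose at least 4-fold. In high calcium, 383 were higher than in low calcium and 464 were lower, and 4 rose at least 4-fold. No biological explanation was tested for these probe sets.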

How the results depend on the processing

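The fit with the replicate number as a block within the 4 arrays compared and the array weights for each group were chosen after seeing the data, and the other settings were planned. Of 4517 alternative values of 222 named-gene results, 4268 kept their side of the threshold, 231 lost the call, 14 gained it and 4 reversed. A reversal was counted only where the main result passed, so the 4268 include sign changes of results that did not pass. An example is the second KLF4 probe set in high calcium versus LacZ, at -0.06 as deposited and 0.08 after quantile normalization. Of 921 alternative values of 42 list calls, 845 kept the call, 76 lost it and 0 reversed. The setting with an estimated correlation ended 40 of the 42 calls, and all other settings together account for 36 losses. In p63+KLF4 versus LacZ, the early differentiation, cornified envelope and EGF receptor lists lost the call at estimated correlations of -0.0028, -0.013 and -0.054. These lie below the preset 0.01, so correlation between genes does not account for those losses. The 40 losses can therefore not be read as an effect of correlation between genes alone.

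Fitted to only the 4 arrays compared, 2174 genes changed in p63+KLF4 versus LacZ and 8690 in high calcium versus low calcium. With array weights the latter count was 8113, and 2907 genes changed in low calcium versus p63+KLF4, where 1258 did without a variance trend. At least 2-fold changes numbered 1338, 954, 1592, 2584 and 182 in the order of comparisons given under the methods, and lists called with an estimated correlation numbered 0, 1, 0, 1 and 0. Lists called in high calcium versus low calcium numbered 7 without dim genes. In low calcium versus p63+KLF4 they numbered 5 under quantile normalization and under median centring, 1 with a pseudocount of 1 or 64, and 7 with the mean of probe sets or without suffixed probe sets. The correlation of 0.077 between the first 2 comparisons was 0.108 under quantile normalization, 0.049 with a pseudocount of 1 and 0.141 without dim genes. Without suffixed probe sets, KRT7 (-0.196), MEOX2 (-0.15) and ASNS (-0.393) in p63+KLF4 versus LacZ and KLF2 (0.593) in high calcium versus low calcium reversed, because another probe set then stands for the gene. Otherwise the cause was not tested.

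Leaving out 1 array at a time, with the lone array of its group assumed to vary like the other groups, gave 3825 to 6125 changed genes in p63+KLF4 versus LacZ, 1919 to 5953 in high calcium versus low calcium, 3530 to 7041 in low calcium versus LacZ, 5635 to 8647 in high calcium versus LacZ and 23 to 3604 in low calcium versus p63+KLF4. In the last, 1 to 7 lists were called. The correlation ranged from 0.053 to 0.1. Signal over background limits the dim genes, since between 28.2% and 32.9% of probe sets on an array read below the pseudocount, where fold changes are compressed.

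The labels give replicates of different groups the same numbers without stating a pairing. Deviations of same-numbered arrays from their group means correlated at 0.66 between LacZ and p63+KLF4 and between -0.09 and 0.01 in the other pairs of groups. Same-numbered LacZ and p63+KLF4 arrays thus deviated together, those of the other pairs of groups did not, and with 2 arrays in a group this does not establish a pairing. With the replicate number as a block, 5414, 4720, 6836, 8550 and 2052 genes changed in the 5 comparisons, and within only the 4 arrays compared the block gave 5952, 8661, 5655, 6470 and 1535. In p63+KLF4 versus LacZ, 4908 of the 5952 were among the 5191 changed genes. The same 4 arrays without the block gave 2174, from a model that takes no account of the deviation these arrays share.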

Other observations

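All tests in this part were chosen after the result they concern was seen, except the test of 6 further BMP-responsive genes. Complement genes rose with calcium. Of 17 measured members 10 rose and 0 fell in high calcium versus low calcium (limma camera adjusted p = 1.5e-06 over 30 tests; adjusted p = 0.33 with an estimated correlation). The proteases C1R and C1S, which start the classical pathway, rose 4.73-fold and 4.86-fold, and CFB and CFI, of the alternative pathway and its control, rose 7.49-fold and 6.68-fold. The list was drawn up after C3 and SERPING1 had been seen among the largest rises, so its direction is not independent evidence. Of 11 genes of antigen presentation 7 rose and 0 fell (camera adjusted p = 7.8e-05; adjusted p = 0.42 with an estimated correlation), with HLA-F 2.23-fold, HLA-E 1.77-fold and HLA-B 1.51-fold higher. Of 22 matrix metalloproteinases 7 rose and 1 fell (camera adjusted p = 0.0085; adjusted p = 0.33 with an estimated correlation): MMP10 rose 2.44-fold and MMP28 2.12-fold, and MMP3 was 2.70-fold lower.

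In p63+KLF4 versus LacZ, MMP28, an epidermal member of that family, rose 35.4-fold, and the collagenase MMP1 was 5.75-fold lower (the list had 2 rises and 6 falls, camera adjusted p = 0.2). Of 28 HOX genes, which record body position, 1 rose and 4 fell (camera adjusted p = 0.041; adjusted p = 0.33 with an estimated correlation), with HOXB2 3.27-fold lower and HOXC13 1.89-fold higher. Some familiar markers, chosen after their values were seen, moved little or did not pass. CDH1, the epithelial cadherin, changed by 0.20 on the log2 scale (limma adjusted p = 0.294) and VIM, the filament protein of mesenchymal cells, by 0.05 (0.438). KRT1 and KRT10, the keratins of the suprabasal epidermis, changed by -0.06 and 0.07 in p63+KLF4 versus LacZ (0.867 and 0.578) and by 0.10 and 0.02 in high calcium versus low calcium (0.785 and 0.889). IVL, involucrin, rose by 1.14 in the latter (0.00148).

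Both KLF4 probe sets moved in opposite directions in p63+KLF4 versus LacZ. Array scaling is argued against, since the second probe set fell by 1.64 ± 0.18 (SE) on the log2 scale beyond the 100 probe sets closest in mean level, which a scaling by array or by intensity moves alike. A candidate explanation is that 1 probe set reads the introduced cDNA and the other the cells' own transcript. Their changes between low calcium and p63+KLF4 differed by 0.81 ± 0.06 (SE), which this explanation allows. It stays open because probe positions were not used here.

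Matrix genes rose in high calcium, and array scaling is argued against, since over the whole list of 34 the median log2 change beyond that of the 100 genes closest in mean level was 0.70 with a spread of 0.10 (median absolute deviation over the square root of n), and 32 of the 34 lay above those genes. More untransduced fibroblasts in the high calcium cultures could raise them. A larger share of cells at LacZ levels is argued against for 8 of the 16 that rose: COL3A1, COL5A2, COL6A2, FBN1, DCN, MFAP2, MFAP4 and TIMP3. These were higher in high calcium than in LacZ under all 3 scalings, which a mixture of LacZ-like and low calcium cells does not give. For the other 8 such a share is argued against by genes abundant in LacZ (mean intensity of at least 1000, at least 4-fold above low calcium, outside the matrix list). The lowest share of LacZ-like cells that any of the 8 needs is 27.5%, for LOXL2, and 41 of 43 abundant genes lay below the level this share gives. The median log2 of measured over needed level was -1.49, with a median absolute deviation of 0.7. However, 29 of the 43 read lower in high than in low calcium, which no such mixture gives, so these genes also changed in another way. OXTR read 5330 in LacZ, 886 in low and 163 in high calcium, where that share needs 2110, and TAGLN read 5430, 785 and 404, where it needs 2060. Both arguments bear only on cells that keep their LacZ levels. Untransduced cells that themselves changed with calcium stay possible for all 16. A response of matrix genes to calcium is a hypothesis that no LacZ group with low or high calcium tests here.

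In low calcium versus p63+KLF4, 5 of 7 BMP-responsive genes fell (camera adjusted p = 0.00041; adjusted p = 0.54 with an estimated correlation), among them ID3 (-1.76), SMAD6 (-1.55) and BAMBI (-1.22), but the list was drawn up after falls had been noticed here, so its direction is not independent evidence. The median log2 change of the 7 beyond that of the 100 genes closest in mean level was -1.28 with a spread of 0.19. Because the 7 were listed after falls had been noticed, this value cannot test array scaling as a cause. Their median change was -1.48 as deposited, -1.32 after quantile normalization and -1.39 after centring. Lower BMP signalling in low calcium, as a hypothesis, predicted before their values were seen that 6 further genes would have a median change of -0.4 or lower. The median was -0.63 with a spread of 0.31, from ID4 (-1.22), SMAD9 (-1.14), NOG (-0.64), MSX2 (-0.62), ATOH8 (-0.12) and MSX1 (-0.09, and not negative under the other scalings), with a median of -0.54 under both other scalings, which meets the prediction, although no gene of the 6 passed alone and the list was not called (camera adjusted p = 0.2; adjusted p = 0.61 with an estimated correlation). Whatever else differed between these groups may account for the fall as well. Among it is the ACTB 3' to 5' ratio (2.11 and 1.82 in p63+KLF4 against 1.5 and 1.36). The GAPDH ratio was 1.07 and 1.02 in p63+KLF4 against 0.958 and 0.928. Against LacZ the noticed genes had a median of 0.96 in p63+KLF4 and -0.76 in low calcium, and the 6 further genes -0.14 and -0.82.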
